A study of Oncorhynchus mykiss with 18 samples.

How the data were processed

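The data are messenger RNA sequencing of whole brains of juvenile rainbow trout. Per the series' design text, 5 fish were kept in each of 6 tanks per diet, and RNA of 2 brains from a tank, taken after 7 days, was mixed in equal amounts. A further 7 days on control food followed the exposure, and the design text places the brain sampling after 7 days without naming the phase, read here as the end of exposure. One library therefore stands for 1 tank, and there were 6 tanks on each of 3 diets. The stranded libraries were sequenced as read pairs of 100 bases, and RNA integrity numbers were at least 6.5 with a mean ± SD of 7.84 ± 0.875, per the labels and the design text.

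Per the submitters' processing notes and the design text, the authors trimmed reads with Trimmomatic to a Phred score of at least 20 and a length of at least 35 bases. They estimated transcript abundance with Salmon 1.10.2 on the USDA_OmykA_1.1 transcriptome and assigned transcripts to genes with GenomicFeatures 1.52.1 and the Ensembl 110 annotation. The version of Trimmomatic and the tool that summed transcripts are not given in the sources used here. The deposited values are estimated counts (expected counts) per gene, not scaled between libraries, for 48460 Ensembl gene IDs and 18 libraries. Of these values, 551186 were not whole numbers. Salmon divides reads shared by near-identical copies among them, and the trout genome holds many duplicated genes, so the level of a single copy is less certain than its counts imply.

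Library columns were matched to tanks by the labels' descriptions, and diets and tank numbers were taken from the titles. Expected counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr with a minimum count of 10, a minimum total of 15 and groups of 6, which left 35146 genes holding 99.9% of the counts and removed 13314. Scaling used TMM factors. One negative binomial model with a term per diet was fitted to all 18 libraries, with 15 residual degrees of freedom, and each of the 3 pairs of diets was tested with edgeR's two-sided quasi-likelihood test. An overall test of any difference among the 3 diets used the same fit. P-values were adjusted by the Benjamini-Hochberg method, and genes were called at an adjusted p under 0.05 without a fold threshold. Normalised levels are CPM, counts scaled to the TMM-adjusted library size, given as mean ± SD over tanks. Standard errors (SE) and 95% intervals of log2 fold changes come from the same test. These choices, and the alternatives not described as added, were fixed before the data were examined.

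Total counts ran from 23517077 to 33647441 per library. At that depth and with 6 tanks per diet, the median SE of a log2 fold change was 0.13 for genes of 10 to 100 CPM and 0.43 for genes under 1 CPM in the comparison of erythromycin with control. The common biological coefficient of variation was 0.299. Pairs of libraries of one diet were checked for duplicates, and the lowest chi-square per degree of freedom was 15.5, far above sampling noise, so each library was counted once.

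The scripts were tested on simulated data drawn from the observed gene means and library sizes of 35146 genes. At each of 4 fold sizes, 50 genes were changed. The recovered shares below hold for data simulated in this way. They are not the power of the tests on the real libraries, where genes can vary together and the number changed is unknown. For erythromycin against control, the edgeR test recovered 26% of genes changed 1.5-fold, 52% at 2-fold, 74% at 3-fold and 84% at 4-fold. For the mixture against control, it recovered 22%, 66%, 84% and 86% at these sizes, and for the mixture against erythromycin 22%, 54%, 76% and 86%. False calls among unchanged genes numbered 2, 2 and 0. Recovery with the tank set in the model, at 1.5-fold and 2-fold, was 38% and 72% for erythromycin against control, 30% and 70% for the mixture against control and 32% and 62% for the mixture against erythromycin, with 13, 9 and 2 false calls.

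Library structure was described with principal components of log2 CPM, with a prior count of 2, for the 500 most variable genes and for all tested genes. The share of variance between diets was tested by exact permutation over all partitions of the libraries. Tank number is the only order the labels give. After the data were seen, tanks 1 to 9 and tanks 10 to 18 were treated as separate tank sets, with 3 tanks of each diet in each set. The set was added to the edgeR model as a factor, and diets were also compared inside each set. The choice of boundary was tested by repeating the search over 13 boundaries in 10000 random orders of the tank numbers within diets. The correlation of fold changes between the 2 antibiotic diets was set beside 20 simulations of unchanged groups. In each simulation all 18 libraries, the controls included, were drawn from 1 mean per gene, each gene independently of the others. The correlation was also set beside all splits of the control tanks into disjoint sets of 3. Both were repeated with the tank set in the model, with simulated means then per gene and tank set. This repeat was added after the data were seen.

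The rule for named genes took called genes with a symbol, members of fixed gene lists and a set of marker genes. Where under 10 genes were called, it took the genes with the smallest unadjusted p. The gene table used here for the same assembly, with 72772 genes, has an empty Ensembl column, and the files do not pair the IDs with names. The 37 gene lists fixed in advance matched 0 genes, and no marker gene could be looked up. The list tests were therefore not run, and each comparison gives only the 2 IDs with the smallest p on each side. The next ones are summarised.

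Alternatives were RLE and upper quartile scaling, no low-count filter, and a filter of at least 1 CPM in at least 6 libraries. Others were DESeq2, limma-voom with sample quality weights, robust dispersions and fits of only the libraries compared. The covariates tried were linear tank number, the first surrogate variable and log2 library size, and each tank was left out in turn. Fits with the tank set, inside each set, with 2 or 3 surrogate variables, with a spline of tank number and with other boundaries were added after the data were seen. The tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0. Permutation tests and plots used Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9.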

Results

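Brain transcripts were counted in 18 libraries of rainbow trout (Oncorhynchus mykiss) fed 1 of 3 diets for 7 days and sampled, as the design text is read here, at the end of that exposure, to ask whether antibiotics in the food alter gene expression in the brain. The control diet carried methanol, the solvent, alone. The erythromycin diet held 1000 µg per g of this macrolide, which blocks bacterial protein synthesis. The mixture diet held 100 µg per g each of erythromycin, ampicillin, a beta-lactam, metronidazole, a nitroimidazole, and ciprofloxacin, a fluoroquinolone. Each diet had 6 tanks, and each library was the pooled RNA of 2 brains from 1 tank, so the spread within a diet is that between tanks. Library totals were 31695439 ± 1335923 counts for control, 30050085 ± 2478449 for erythromycin and 28702082 ± 3258562 for the mixture (mean ± SD, n = 6 each). They did not differ between diets in an exact permutation test (p = 0.144). Of 48460 genes, 46151 had a count in some library and 35146 were tested. A library held counts for 40213 to 41345 genes. The 1841 genes over 100 CPM held 49.1% of the counts, and the 10 most abundant genes of a library held 3.25% to 4.54%.

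The libraries did not separate by diet. On the first principal component of the 500 most variable genes, diet accounted for 6.62% of the variance (exact permutation p = 0.601). Leaving out single tanks moved this share most for control tank 16 (17.4%), mixture tank 9 (10.8%), erythromycin tank 11 (10.2%), control tank 4 (2.46%) and erythromycin tank 3 (2.22%), with exact permutation p from 0.262 to 0.856 over all tanks left out. Over all tested genes and components diet accounted for 10.4% (exact permutation p = 0.715). They did separate by tank number. On the first component of the 500 most variable genes the tank set held 27.0% of the variance, and over all components of those genes 8.45% (exact permutation p = 0.0350 and 0.0313, adjusted p = 0.0525 for both over 9 measures). The separation was larger over all tested genes, where the set held 17.2% over all components (exact permutation p = 0.0005). On the first component of all tested genes, which held 22.6% of the variance, tanks 1 to 9 scored -38.9 ± 29.1 and tanks 10 to 18 scored 38.9 ± 25.5 (SD, n = 9 each). Antibiotic mixture tank 6, at 25.3, and control tank 16, at -3.76, lay on the other side of 0 from the rest of their sets. The tank set accounted for 69.5% of the variance of this component (exact permutation p = 0.0005). Inside the sets, a relation of the component to tank number was not shown, and 9 tanks per set leave a moderate one open. In tanks 1 to 9, Pearson's r was 0.192 and Spearman's rho 0.150 (exact p = 0.644 and 0.708), and r was 0.0535 without the tanks at either end. In tanks 10 to 18, r was -0.394 and rho -0.450 (exact p = 0.288 and 0.230), and r was -0.0958 without the end tanks. The adjusted p-values over these 2 relations were 0.576 or more for r and 0.460 or more for rho. The boundary after tank 9 was chosen after the data were seen. It gave the largest share of the within-diet variance of 13 boundaries tried (19.2%), and a search over as many boundaries gave a share as large in random tank orders with a permutation p of 0.001.

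**Figure D1:**
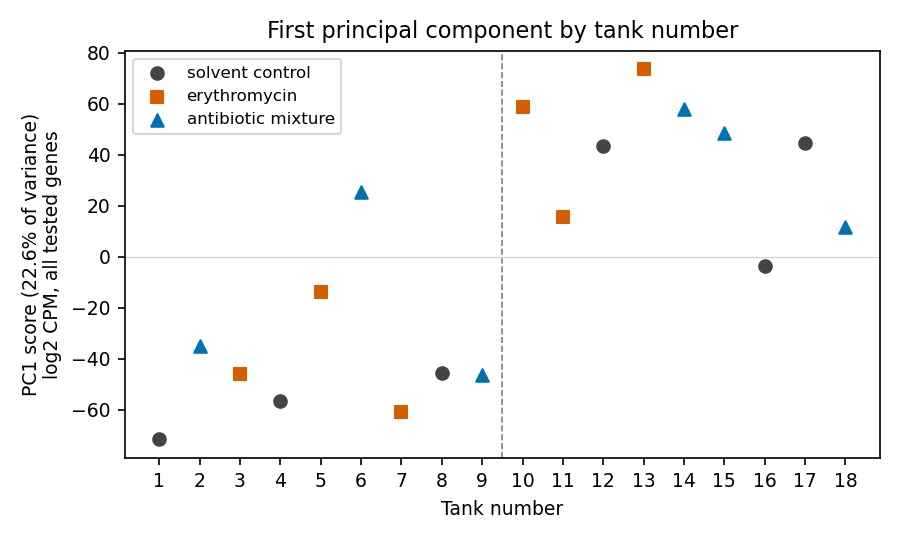
Score of each library on the first principal component of log2 CPM of all tested genes (y axis, no unit) against tank number (x axis), with symbols and colours for the 3 diets and a dashed line after tank 9. Tanks 1 to 9 have a mean score of -38.9 and tanks 10 to 18 a mean score of 38.9, with mixture tank 6 and control tank 16 on the other side of 0.

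With diet in the edgeR model, 12620 genes, 35.9% of those tested, differed between the tank sets at an adjusted p under 0.05. Of these, 6701 were higher and 5919 lower in tanks 10 to 18, and 873 differed more than 2-fold. Upper quartile scaling reversed this majority, with 6149 higher and 7058 lower. The most abundant genes were mostly lower in tanks 10 to 18: 925 of the 1150 called genes over 100 CPM fell. Of the 4052 called genes at 1 to 10 CPM, 2765 rose, and these tendencies held under all 3 scalings. The gene ENSOMYG00000018795 rose from 12.2 ± 1.36 to 19.1 ± 1.73 CPM (log2 fold change 0.64, SE 0.06, adjusted p = 5.1e-05), and ENSOMYG00000029967 fell from 655 ± 46.2 to 478 ± 30.8 CPM (log2 fold change -0.45, SE 0.05, adjusted p = 0.000111; SD, n = 9 each). In both genes every library of one set lay beyond every library of the other, which the choice of genes by small p favours. The 10 most abundant genes held 4.32 ± 0.198% of the counts in tanks 1 to 9 and 3.53 ± 0.192% in tanks 10 to 18 (exact permutation p = 0.00025, the smallest these splits can give). Linear tank number, a covariate planned before the data were seen, was itself associated with 5489 genes. The diets were balanced over the sets, with control tanks 1, 4 and 8, erythromycin tanks 3, 5 and 7 and mixture tanks 2, 6 and 9 in the lower-numbered one. Each comparison below therefore also gives its gene counts with the tank set in the model. Fold changes are from the model without it unless stated.

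Erythromycin against control asked whether the single antibiotic at the higher dose altered the brain transcriptome. Among genes higher on erythromycin, those with the smallest p-values were ENSOMYG00000024798 and ENSOMYG00000000049. Among genes lower on it they were ENSOMYG00000043325 and ENSOMYG00000027403. None of the 4 passed correction in edgeR (adjusted p = 0.896). DESeq2 called ENSOMYG00000024798 (adjusted p = 0.0307) and, with the tank set added after the data were seen, all 4 (adjusted p = 0.0236 to 0.0280). ENSOMYG00000024798 measured 13.9 ± 19.6 CPM on erythromycin and 0.392 ± 0.273 CPM on control (SD, n = 6 each; log2 fold change 5.12, SE 1.07; 4.29, SE 1.18, with the tank set in the edgeR model). Its level came from erythromycin tanks 3, 5 and 7, at 50.4, 21.4 and 9.63 CPM, while tanks 10, 11 and 13 stayed at 0.693 to 0.829 CPM, close to the highest control tank at 0.797. Inside tanks 1 to 9 its log2 fold change was 7.11 (SE 0.88, edgeR adjusted p = 0.0178), and inside tanks 10 to 18 it was 0.31 (SE 0.76, edgeR adjusted p = 0.953). The difference between the sets did not pass correction in edgeR (adjusted p = 0.390). ENSOMYG00000000049 measured 5.66 ± 0.635 against 3.79 ± 0.489 CPM (log2 fold change 0.58, SE 0.13), with all 6 erythromycin tanks above the control median. ENSOMYG00000043325 measured 6.41 ± 0.633 against 9.06 ± 0.884 CPM (log2 fold change -0.50, SE 0.11). ENSOMYG00000027403 measured 44.6 ± 4.40 against 56.3 ± 4.01 CPM (log2 fold change -0.33, SE 0.08). In both, all 6 erythromycin tanks lay below the control median. The choice of genes by small p favours such one-sided placing. The 10 genes with the smallest p, 7 higher and 3 lower, ran from 0.33 to 5.12 in absolute log2 fold change.

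Across all 35146 genes, edgeR called 0 between erythromycin and control. At an unadjusted p under 0.05 it found 1727 genes, 938 higher and 789 lower, where other splits of the 12 tanks gave a median of 978. A rate of 5% of the genes tested would be 1757. DESeq2 called 3 genes, of which 2 were at 0 in 6 or more of the 12 libraries, and limma-voom called 0. With the tank set in the model edgeR called 0 genes, with 3450 at an unadjusted p under 0.05 (1656 higher, 1794 lower; smallest adjusted p = 0.485). DESeq2 then called 31, 14 higher and 17 lower. The 95% interval of the fold change lay within 2-fold for 79.7% of genes, for 96.7% of those at 10 to 100 CPM and for 28.0% of those under 1 CPM. The 20 most abundant genes, with 5.98% of the counts, all had intervals within 2-fold, and their log2 fold changes ran from -0.23 to 0.21.

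The mixture against control asked the same of the 4 antibiotics given together at a lower dose each. ENSOMYG00000007414, at 1.34 ± 0.342 against 0.736 ± 0.151 CPM (SD, n = 6 each; log2 fold change 0.87, SE 0.22), and ENSOMYG00000011755, at 12.4 ± 2.09 against 7.33 ± 1.63 CPM (log2 fold change 0.76, SE 0.20), had the smallest p among genes with higher values. ENSOMYG00000016443, at 2.07 ± 0.837 against 9.08 ± 8.24 CPM (log2 fold change -2.13, SE 0.52), and ENSOMYG00000008316, at 112 ± 19.4 against 185 ± 42.5 CPM (log2 fold change -0.71, SE 0.17), had the smallest p among those with lower values. In each of the 4, all 6 mixture tanks lay on one side of the control median, which the choice of genes by small p favours. None of the 4 passed correction in edgeR (adjusted p = 0.992). The control mean of ENSOMYG00000016443 came from tanks 4, 8 and 12, at 8.99, 20.0 and 18.4 CPM. Control tanks 1, 16 and 17, at 2.55, 2.60 and 2.01 CPM, lay inside the mixture range of 0.993 to 3.04. The erythromycin tanks were also low for this gene, at 1.39 to 3.14 CPM. DESeq2 with the tank set called it for erythromycin against control (log2 fold change -2.19, adjusted p = 0.0236). ENSOMYG00000008316 had a log2 fold change of -0.78 (SE 0.20) inside tanks 1 to 9 and -0.64 (SE 0.20) inside tanks 10 to 18, while ENSOMYG00000007414 had 0.45 (SE 0.30) and 1.24 (SE 0.29). The 10 genes with the smallest p held 3 higher and 7 lower.

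In all, edgeR called 0 genes between the mixture and control and found 782 at an unadjusted p under 0.05, 335 higher and 447 lower, where other splits of the 12 tanks gave a median of 1017. Without mixture tank 2 that number was 1350. DESeq2 called 2 genes, both at 0 in 6 or more of the 12 libraries, and limma-voom called 0. With the tank set in the model, edgeR called 0 genes and found 1566 at an unadjusted p under 0.05, and DESeq2 called 1. The interval lay within 2-fold for 80.5% of genes and for 98.4% of those over 100 CPM, and the 20 most abundant genes ran from -0.29 to 0.09 in log2 fold change.

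**Figure D2:**
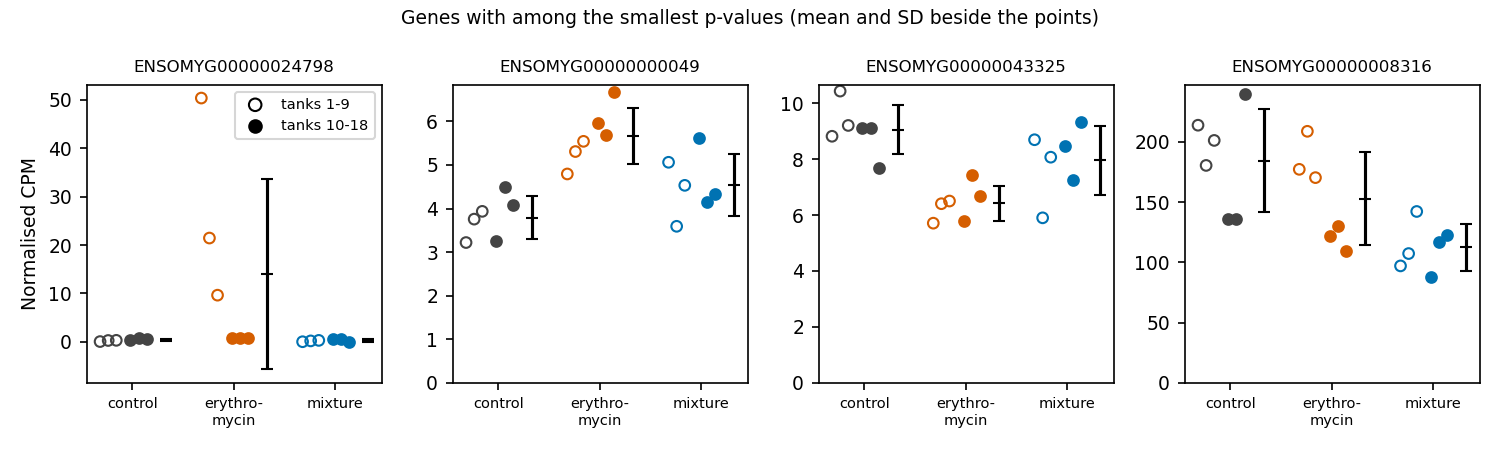
Normalised CPM (linear y axes) of 4 named genes in each of the 18 libraries by diet, with open points for tanks 1 to 9, filled points for tanks 10 to 18, and the mean ± SD of each diet (n = 6) beside them. ENSOMYG00000024798 reaches 50.4, 21.4 and 9.63 CPM in erythromycin tanks 3, 5 and 7 and stays at or below 0.829 CPM in every other library, while the means of the other 3 genes differ by less than 2-fold between diets.

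The mixture against erythromycin compared the antibiotic diets directly. ENSOMYG00000049691, at 0.910 ± 0.398 against 0.240 ± 0.150 CPM (SD, n = 6 each; log2 fold change 1.89, SE 0.48), and ENSOMYG00000057461, at 1.25 ± 0.472 against 0.453 ± 0.237 CPM (log2 fold change 1.44, SE 0.38), had higher values on the mixture. ENSOMYG00000024798, at 0.249 ± 0.236 against 13.9 ± 19.6 CPM (log2 fold change -5.77, SE 1.13; -5.03, adjusted p = 0.995, with the tank set in the edgeR model), and ENSOMYG00000033224, at 0.288 ± 0.0748 against 1.08 ± 0.729 CPM (log2 fold change -1.89, SE 0.40), had lower values. None passed correction in edgeR (adjusted p = 1.00), and the other 3 of these genes averaged 1.25 CPM or less in either diet. DESeq2 called ENSOMYG00000024798 (log2 fold change -5.80, adjusted p = 0.00185), also with the tank set (log2 fold change -5.69, adjusted p = 0.00662). Inside tanks 1 to 9, ENSOMYG00000024798 passed in edgeR (log2 fold change -7.56, SE 0.92, adjusted p = 0.0147), inside tanks 10 to 18 it did not (log2 fold change -1.05, SE 0.81, adjusted p = 1.00), and the difference between the sets did not pass (adjusted p = 1.00). EdgeR called 0 genes in all, with 935 at an unadjusted p under 0.05, 403 higher and 532 lower, where other splits of the 12 tanks gave a median of 1221. The real number was 1744 without mixture tank 2 and 1473 without mixture tank 15. DESeq2 called 4 genes, of which 2 were at 0 in 6 or more of the 12 libraries, and limma-voom called 0. With the tank set in the model, edgeR called 0 genes, with 1348 at an unadjusted p under 0.05, and DESeq2 called 4. The interval lay within 2-fold for 81.6% of genes.

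The overall edgeR test of any difference among the 3 diets called 0 genes (smallest adjusted p = 0.460), with 1046, or 2.98%, at an unadjusted p under 0.05. With the tank set in the model, 2068 genes reached that level and 0 were called. The effect of a diet did not differ between the tank sets at an adjusted p under 0.05 in edgeR for any gene in any of the 3 comparisons; at an unadjusted p under 0.05, 711, 1016 and 950 genes differed.

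Across genes, which are not independent replicates, the log2 fold changes of the 2 antibiotic diets against control correlated with r = 0.592 (covariance 0.0685), and 73.2% of genes had the same sign. Both comparisons use the same 6 control tanks. Simulations of unchanged groups, with a simulated control group shared by both comparisons, gave a mean r of 0.502, from 0.475 to 0.519. Their mean covariance was 0.0587, and 66.6% of genes had the same sign. The observed covariance exceeded the mean simulated one by 0.00981, and by 0.00505 (0.0430 observed) among genes with at least 1 CPM in at least 6 libraries. Genes were drawn independently in these simulations and in those with the tank set below. The simulated range thus leaves out variation that genes share, and an excess over it cannot show a shared response to the diets. With single tanks left out the observed r ran from 0.505 to 0.671. With disjoint sets of 3 control tanks for each diet, r was 0.0259 and the covariance 0.00372. In a model with the tank set, r was 0.595 and the covariance 0.0682, against a mean of 0.496 and 0.0516 in simulations that kept the tank effects, and the covariances differed by 0.0167. Disjoint control sets then gave an r of 0.0736 and a covariance of 0.0136.

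**Figure D3:**
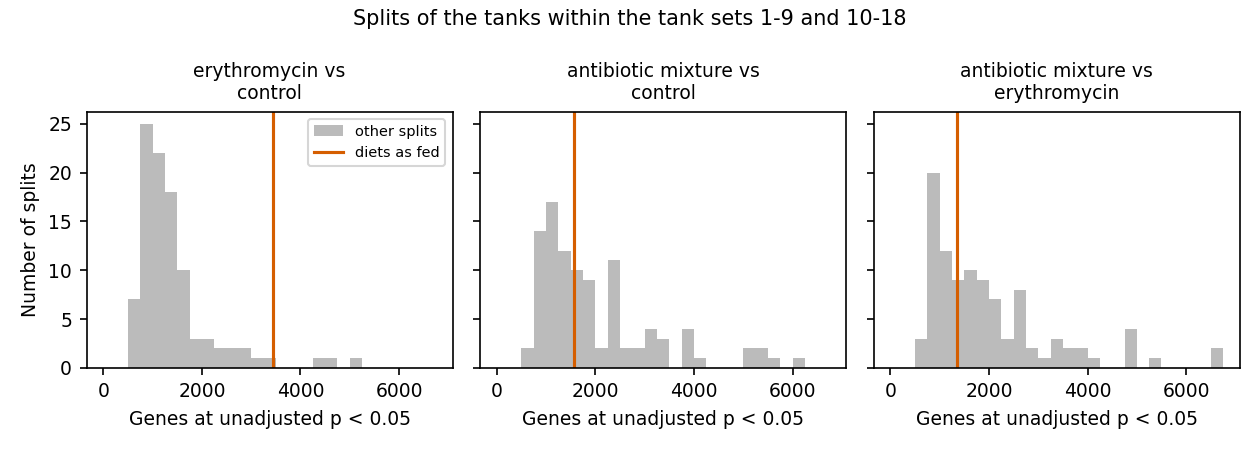
Number of genes at an unadjusted p under 0.05 with the tank set in the edgeR model (x axes) in 99 other splits of the 12 tanks of each comparison made inside the tank sets (grey bars, number of splits on the y axis), with the diets as fed as an orange line. The diets as fed gave 3450, 1566 and 1348 genes. The other splits had medians of 1203, 1541 and 1651, and the highest gave 5162, 6180 and 6747.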

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

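The rule for genes high in a single library, the search over tank boundaries, the linear tank number set beside the tank set, and the tank set itself were chosen after the data were seen. In each diet's 6 tanks, library measures and the levels of the named genes were searched for a library far from the others. Of 48 groups of 6 values, 3 held one, where a rate of 1 in 20 would give 2.4. That rate is only a rough guide here. Counts of genes high in a single library are mostly 0, and the named genes were picked by small p in these tanks. Control tank 1 had counts for 40413 genes, against 40722 in the nearest other control tank. Mixture tank 9, with 40213, and erythromycin tank 7, with 40396, had fewer. Tanks 1 to 9 had 40590 ± 275 genes and tanks 10 to 18 had 40961 ± 239 (SD, n = 9 each). Mixture tank 18 had 2 genes of at least 10 CPM and at least 10 times the next library, where the other mixture tanks had 0.

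Control tank 4 had 23 such genes, against at most 1 in another control tank. They measured 11.7 to 353 CPM there and took 0.150% of its counts, against a median of 0.00176% and at most 0.00509% elsewhere. The highest, ENSOMYG00000075984, singled out after its values were seen, measured 353 CPM against 4.62 in the next library. A varying amount of one tissue or cell type in the pooled brains is a possible explanation: in the other 17 libraries, with diet and tank set removed, the 23 genes rose and fell together, with a mean pairwise Spearman correlation of 0.184. The 95th percentile of 10000 random gene sets of like level was 0.0388 and the highest 0.108. Genes under shared regulation would do the same, and without gene names the tissue stays unknown, so a response of the fish in this tank also stays open, as untested.

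The difference between tanks 10 to 18 and tanks 1 to 9 covered 12620 genes. Of 100 splits of the tanks into sets of 9 with 3 of each diet, only the real one gave as many genes, and the highest other, which kept 7 of tanks 1 to 9 together, gave 9719, so chance alone is unlikely, although the boundary was picked from the data. With log2 library size in the model, 94.4% of the called genes were still called, and without the 100 most abundant genes 99.8% of the other called genes were, which argues against depth or a few abundant genes as the whole cause. For a gradual drift along the tank numbers, linear tank number called 0 genes with the tank set in the model, while the set called 2822. Among those were 20.4% of the 12620 genes, and linear tank number alone called 5489. The boundary was picked from these data, and only a straight line was set beside it. This test therefore cannot decide between a step and a drift. A difference in RNA extraction, library or sequencing batch, or in sampling or holding of the fish, could each produce such a pattern. The labels used here give none of these per tank, so all stay open.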

How the results depend on the processing

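EdgeR called 0 genes between diets under every scaling, filter, covariate, dispersion setting and left-out tank tried on all 18 tanks or on the 12 compared, and limma-voom called 0 in its 2 fits, with sample quality weights and with the tank set. EdgeR also called 0 in the overall test under its 8 alternatives and every left-out tank. Leave-one-out counts ran from 0 to 0. DESeq2 called 3 genes for erythromycin against control, 2 for the mixture against control and 4 for the mixture against erythromycin, and 31, 1 and 4 with the tank set added. Most of its calls without the set were genes at 0 in 6 or more of 12 libraries (2, 2 and 2); with the set, 1 of the 31, the 1 call for the mixture against control and 2 of the 4 for the mixture against erythromycin were. The cause of the difference from edgeR was not tested. Inside tanks 1 to 9, edgeR called 1, 0 and 1 genes, and inside tanks 10 to 18 it called 0 in each. The fits with the tank set, inside the sets, with 2 or 3 surrogate variables, with a spline and at other boundaries were added after the data were seen. Genes at an unadjusted p under 0.05 for erythromycin against control numbered 1158 to 2310 with a tank left out, and 3478 with linear tank number.

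Of 451 alternative values for 12 pairs of named gene and comparison, 442 kept their direction and side of the threshold, 9 passed it and 0 changed direction. The pairs were picked for small p in these libraries, and the values are refits of the same libraries. A kept direction was thus favoured in advance and is not independent support. The 12620 genes differing between the tank sets became 11794 to 13771 under other scalings, filters, DESeq2 or a library-size term, and 10940 to 13937 with a tank left out. Boundaries after tanks 3, 4, 5, 6, 7 and 8 called 1, 23, 2, 0, 2645 and 8258 genes. Those after tanks 10 and 11 called 8525 and 9625, and those after tanks 12 to 15 called 0. The place of any step is therefore known only to within a few tanks. The correlation of the antibiotic diets' fold changes was 0.505 to 0.671 with a tank left out and 0.0259 with disjoint controls, which no longer share libraries, or 0.0736 with the tank set added. The diet share of the first component ran from 2.22% to 17.4% with a tank left out. A rule of 5 CPM and 5 times the next library gave 60 genes high in 1 library in place of 28, with 43 in control tank 4 and 12 in mixture tank 18. No paired analysis was possible because each tank number occurs once. The tests of the 37 gene lists were not run, since no ID could be paired with a name.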

Other observations

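The tank set in the model below was chosen after the data were seen. For the counts of genes called between diets, all of 100 splits of the tanks gave as many genes as the real ones, since the real counts were 0. The highest other splits called 4023 genes for erythromycin against control, 0 for the mixture against control and 4594 for the mixture against erythromycin. The splits that called so many genes point to a structure of the samples: the highest in each of the comparisons with erythromycin put 1 of the 6 tanks numbered 1 to 9 on one side and 5 on the other, and so nearly followed the tank sets.

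With the tank set in the model and tanks regrouped only inside the sets, the real diets gave 3450 genes at an unadjusted p under 0.05 for erythromycin against control. Of 100 such splits, 4 gave as many, the real one included. The other splits gave a median of 1203, and the highest other gave 5162. In the model without the tank set, fixed before the data were seen, 19 of 100 splits reached the real 1727 genes, and the highest other gave 12024. For the mixture against control, in the model with the tank set, 50 of 100 splits reached its 1566 genes (median other 1541, highest other 6180). For the mixture against erythromycin, 61 of 100 reached 1348 (median other 1651, highest other 6747). The 4 of 100 for erythromycin fall under 1 in 20 taken alone. The planned linear tank number, which needs no boundary, gave a like count of 3478 genes, for which splits were not run. The 4 of 100 come from 1 of 3 comparisons, with no correction for that number, so chance stays open. For erythromycin against control, edgeR called 0 genes with and without the tank set. DESeq2 called 3 without it and 31 with it.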
